A study of Arabidopsis thaliana with 24 samples.

How the data were processed

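Leaves of 6-week-old Arabidopsis thaliana plants were infiltrated with 1 µM flg22, a peptide from bacterial flagellin that plants perceive as a sign of infection, or with water, and were harvested 4 h later. Biotin-labelled cRNA was hybridised to Affymetrix ATH1 arrays. There were 4 genotypes: the wild type Col-0, the knockouts erf104 and mpk6, and a line that expresses the ethylene response factor ERF104 from the 35S promoter (35S::ERF104). Each genotype and treatment had 3 arrays, which makes 24 arrays in 8 groups. Groups and replicate numbers were taken from the sample titles.

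The value table holds 1 linear intensity per probe set and array, deposited by the authors. All values are above 0, and the mean after trimming 2% of the values at each end was about 500.0 on every array, so the arrays had been scaled to that mean. The software that summarised probes into probe sets is not given in the sources used here. A normalized table exported by the authors from Genespring GX 7.3.1 holds values per group only: a ratio to the median of each probe set, the mean intensity, the lowest and highest intensity, and the detection calls (present, marginal or absent) that occurred in the group. The authors' ratio and calls, in units of ratio and call letters (other), come with no value per array. In that table the mean intensity of erf104 flg22 equals the mean of replicates 1 and 3 within 0.1% for 86.1% of the probe sets, and the mean of all 3 replicates for 0.11%. In the other 7 groups the mean of all 3 replicates matched within 0.1% for 87.3% to 99.7% of the probe sets. The authors' group values were therefore made from 23 arrays, without erf104 flg22 replicate 2.

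The value table was used for every test. Intensities were taken to log2 with no pseudocount. The 64 control probe sets of the 22810 in the table were left out, which leaves 22746 probe sets tested. The series text states a filter on calls in 50% of the arrays considered; calls per array are not given in the sources used here, so that filter could not be applied and no filter was used. Probe sets were named by the locus in the authors' table and by the symbol of that locus in the RefSeq gene table; 21685 probe sets carry no suffix for matching several genes. No coordinates are given.

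Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Changes are on the log2 scale, each with the standard error (SE) of the fit. That SE uses limma's moderated variance, so it can be smaller than the spread of a single gene over its arrays would give. Counts are also given with a change of more than 3-fold, the fold threshold of the series text. The flg22 response was fitted in each genotype on its 6 arrays, as the series text states for the authors' work. The difference between the flg22 response of a mutant or transgenic line and that of Col-0 (the interaction) and the differences from Col-0 under each treatment were fitted on all 24 arrays. ERF104 and MPK6 were tested against Col-0 in the lines that target them. A composite list was the union over genotypes of probe sets past both thresholds. Overlaps were compared with simulated unchanged groups (100 draws) because the comparisons share arrays. The choices named so far, the alternatives below and the 23 gene lists were fixed before the data were examined. The fits of 23 arrays, given beside those of 24, and the other additions named in the closing section were chosen after the data had been seen.

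The 23 lists, with 395 genes of which 358 have a suffix-free probe set, covered immune signalling and early pattern-triggered response, WRKY transcription factors, ethylene biosynthesis, ethylene perception and signalling, ethylene response factors, ethylene and jasmonate defence outputs, jasmonate biosynthesis and response, salicylic acid and systemic acquired resistance, the group of tryptophan, camalexin and indole glucosinolates, phenylpropanoid and lignin, flavonoid and anthocyanin, photosynthesis, auxin response and transport, the MAP kinase cascade, ER chaperones, heat shock, abscisic acid and cold, the circadian clock, senescence, and markers of guard cells and the stomatal lineage, of vascular tissue, of trichomes, and of roots and flowers. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, with the correlation estimated from the data, and with fry, adjusted over the lists within each comparison. A gene with several probe sets was taken by its brightest one.

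Genes named in the text follow a rule: ERF104 and MPK6 throughout; the 10 largest rises and 10 largest falls for the flg22 response in Col-0 and for 35S::ERF104 against Col-0 under water, and 5 of each elsewhere, among probe sets past the threshold that match 1 gene and whose arrays do not overlap between groups; up to 2 members of each list per direction; and FRK1, WRKY33, ACS6, PR1, PDF1.2a and PDF1.2b everywhere. Among the largest changes, names were dropped only from the bottom of each rank. For the flg22 response in erf104, where the fit of 6 arrays called no gene, the rule was applied to the fit of 5 arrays after the data had been seen. Where a gene was called absent on every array of the lower group, its fold is a lower bound: the lower group was set, on each array, to at least the lowest signal among probe sets called present throughout that group. No fold is given where both groups were called absent. Where only some arrays of the lower group were called absent, no bound was set, so such a size can rest on signals below that level. Signal over background takes the place of read depth here, and the number of arrays limits the precision.

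The fits were tested on simulated data with the arrays' own noise and known changes in 50 probe sets per fold. With the residual SD of each probe set as noise, the fits recovered 0% to 16% of 2-fold, 0% to 54% of 4-fold, 14% to 48% of 8-fold and 34% to 86% of 32-fold changes. With limma's moderated SD, they recovered 0% to 32%, 0% to 74%, 12% to 56% and 42% to 90%. Each fit made 0 to 13 false calls. The 32-fold size and the moderated SD were added after the first runs. In a simulated Col-0 response, camera found the 1 list that had been shifted and no other. The noise there was independent between probe sets, so this does not test the preset inter-gene correlation.

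Alternatives tried were quantile normalization, centring on the median, a pseudocount of 9.18 (the 10th percentile of the values), eBayes without the trend, 1 fit of all 24 arrays, only the groups of a contrast, the replicate number as a block, a filter on detection calls per group, a 2-fold threshold, the methods' ANOVA with and without adjustment, and leaving out each array in turn. Arrays were left out in turn only from the groups compared, also where the fit held all 24. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.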

Results

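RNA from infiltrated leaves was measured on 24 ATH1 arrays, with 3 arrays for each of Col-0, erf104, mpk6 and 35S::ERF104 under water and under flg22. Median signals ran from 133 to 302 scaled units. The number of probe sets called present or marginal on every array of a group ran from 2572 in Col-0 water and 5659 in Col-0 flg22 to 12412 in 35S::ERF104 flg22, so low signals were measured least well in the wild type. Correlations between arrays of one group, across probe sets, were 0.61 to 0.73 in Col-0 water, 0.73 to 0.84 in Col-0 flg22 and 0.84 to 0.93 in the groups of the other genotypes apart from erf104 flg22. In erf104 flg22, replicate 2 correlated with every other array at 0.22 to 0.25, and the authors' group values leave it out. Values from all 24 arrays are given first. For counts and for the genes followed throughout, values from 23 arrays, without that replicate, stand beside them where that array is in a group compared.

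**Figure D1:**
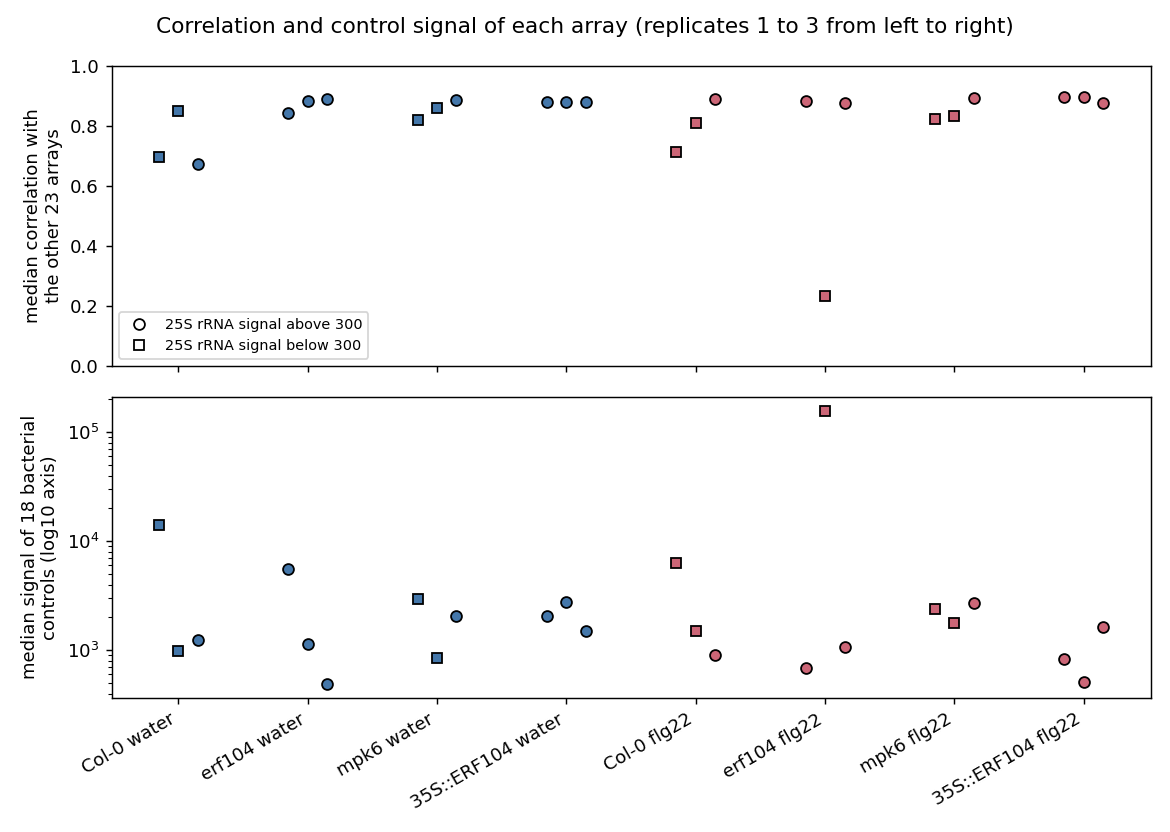
Median correlation of each array with the other 23 (upper panel) and median signal of 18 bacterial control probe sets in scaled units on a log10 axis (lower panel), per group, with circles for arrays whose 25S rRNA signal is above 300 and squares for those below. The array erf104 flg22 replicate 2 lies at a median correlation of 0.234 and a control signal of 157831, and the next highest control signal is 14012.5.

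The signals of ERF104 and MPK6 were compared first, as a check of the genotypes. ERF104 (AT5G61600) had a signal of 189 ± 115 (SD of 3 arrays) in Col-0 water, where it was called absent, and 27010 ± 3714 in 35S::ERF104 water, where it was at least 95-fold higher (limma adjusted p 9.55e-07). Under flg22, where it was called present on some Col-0 arrays, the log2 difference was 7.44 ± 0.674 (SE; adjusted p 9.05e-07). In erf104 the signal was 33.3 ± 16.7 under water. Against Col-0 water both groups were called absent, so no size is given (adjusted p 0.118; 23 arrays 0.011). Under flg22 the difference did not pass (adjusted p 0.344). With 23 arrays it passed (adjusted p 0.00199), and ERF104 was at least 4.27-fold lower in erf104. MPK6 (AT2G43790) had a signal of 1138 ± 402 in Col-0 water and 348 ± 105 in mpk6 water, a log2 difference of −1.69 ± 0.333 (adjusted p 0.356; 23 arrays 0.0579). Under flg22 it was −1.47 ± 0.333 (adjusted p 1.00; 23 arrays 0.257). The 3 arrays of each knockout and of Col-0 did not overlap in the gene they target under water, and mpk6 kept a signal called present on all arrays. Adjusted over these 6 tests alone, a choice made after the values were seen, all 6 differences passed, with adjusted p up to 0.00176, that of ERF104 in erf104 under water between groups called absent. Neither ERF104 nor MPK6 passed the test for a response to flg22 in Col-0 (log2 change −0.05 and 0.81; adjusted p 0.992 and 0.417).

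**Figure D2:**
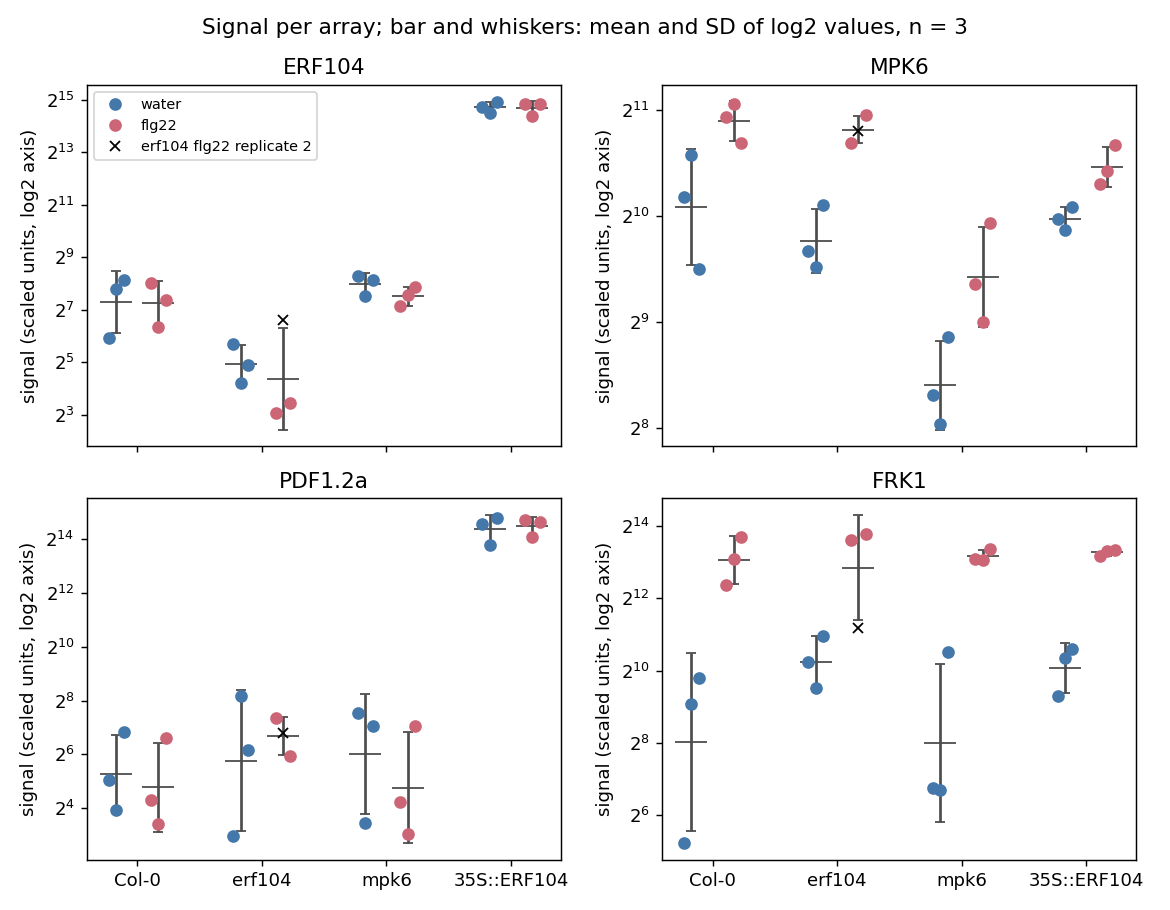
Signal of ERF104, MPK6, PDF1.2a and FRK1 on each array in scaled units (log2 axis) by genotype and treatment, with the mean and SD of the log2 values of 3 arrays; a cross marks erf104 flg22 replicate 2, which is included in the mean. ERF104 and PDF1.2a lie far above the other genotypes in 35S::ERF104 under both treatments, MPK6 is lowest in mpk6, and FRK1 is higher under flg22 than under water in each genotype.

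The flg22 response in Col-0 asks which transcripts the peptide changes in the wild type after 4 h. Of 22746 probe sets, 422 passed, of which 359 rose and 63 fell; 331 rose and 54 fell by more than 3-fold. At an unadjusted p under 0.05 there were 2705. The count ran from 239 (without Col-0 flg22 replicate 2) to 681 (without Col-0 water replicate 3) when 1 array was left out. Without the trend in the variance prior limma called 0, with 2145 at an unadjusted p under 0.05. The median of all probe sets was −0.39 on the log2 scale in this comparison and −0.02 after either quantile normalization or centring on the median. Falls are therefore read against that shift: after centring, 273 rose and 1 fell. After quantile normalization, which also removes the shift, 84.0% of the calls were rises, against 85.1% in the main fit. The share of falls thus depends on how the shift is removed. Among the largest rises, AT1G30700 rose by 5.65 ± 0.447 (SE; adjusted p 4.65e-08) and the receptor-like kinase gene FRK1 (AT2G19190) by 5.04 ± 0.695 (adjusted p 7.15e-05). The signals of FRK1 in Col-0 water were 37.2, 534 and 879, with an SD of 2.45 on the log2 scale. For genes called absent in Col-0 water only a bound can be given: AT2G44370 was at least 18.8-fold higher under flg22, AT3G18250 at least 15.7-fold, AT1G49000 at least 13.8-fold, AT4G36430 at least 9.83-fold, AT2G36210 at least 6.64-fold, AT1G26420 at least 6.34-fold, CYP81F2 (AT5G57220) at least 4.55-fold and CCR2 (AT1G80820) at least 2.70-fold. These genes kept their call when any 1 array was left out, except CYP81F2 (adjusted p 0.126 without Col-0 flg22 replicate 3) and CCR2 (0.159 without Col-0 flg22 replicate 2). The falls rest on few arrays. HAT1 and ER, at least 4.35-fold and 3.63-fold lower, and BGLU8 (−3.72), ZIFL1 (−3.49), IAA1 (−3.12) and AT1G30250 (8.60-fold lower) lost their call when 1 of 3 to 5 of the 6 arrays was left out. GolS2, at least 4.79-fold lower, did so too. E13L3 (AT5G08000) kept it, with a change of −3.03 ± 0.568 (adjusted p 0.00278).

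Among the fixed gene lists, ranked by camera p, the response in Col-0 was strongest in immune signalling. Of 26 measured members, 8 rose and 0 fell over all probe sets, 13 rose adjusted over the list alone, and the median log2 change was 1.60 (camera adjusted p 1.34e-23). FRK1 (5.04) and PUB23 (4.73) had the largest rises past the threshold. Phenylpropanoid and lignin genes followed, with 7 of 16 rising (13 adjusted over the list alone, median 1.43, camera adjusted p 4.22e-21), PAL1 by 3.11. Of the ER chaperones 6 of 10 rose (9 adjusted over the list alone, median 1.53, camera adjusted p 5.00e-17), ERDJ3B by 1.99 and BIP3 by at least 3.59-fold (adjusted p 0.107 without Col-0 flg22 replicate 3). Of the WRKY genes 5 of 20 rose (9 rose and 1 fell adjusted over the list alone, median 1.11, camera adjusted p 6.11e-11), WRKY17 by 3.77 and WRKY22 by 3.52. In the tryptophan, camalexin and indole glucosinolate list 4 of 20 rose (8 adjusted over the list alone, median 0.92, camera adjusted p 1.70e-07), TSA1 9.88-fold. These 5 lists kept their call with the correlation estimated from the data, at p 0.0107 for immune signalling and 0.0369 for the other 4.

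Further lists passed camera in Col-0 at the preset correlation alone. Jasmonate genes were shifted up (median 0.45, adjusted p 0.000129; p with estimated correlation 0.112), and 2 of 19 rose (3 adjusted over the list alone), LOX3 by 3.01 and JAZ1 by 1.64 (adjusted p 0.137 without Col-0 flg22 replicate 2). The MAP kinase cascade was shifted up by its mean of 0.22 with a median of −0.02 and 0 of 33 members past the threshold (adjusted p 0.00101; p with estimated correlation 0.0584). Photosynthesis genes had a median of −0.78 with 26 of 27 members negative and 0 past the threshold (adjusted p 0.000457; p with estimated correlation 0.521). Auxin genes had a median of −1.27, with 1 of 22 falling (adjusted p 0.00237; p with estimated correlation 0.186). Abscisic acid and cold genes had a median of −1.13, with 1 of 13 falling, ERD10 by −1.84, a call lost without Col-0 flg22 replicate 2 at 0.229 (camera adjusted p 0.000711; p with estimated correlation 0.0794). These medians include the shift of −0.39 of all probe sets. The other 13 lists did not pass. Their adjusted camera p was 0.0513 for salicylic acid, where 1 of 23 members rose (CBP60G, 8.59-fold), and 0.0513 for heat shock. It was 0.0617 for ethylene response factors, 0.0692 for ethylene biosynthesis, where ACS2 rose by at least 2.70-fold (0.215 without Col-0 flg22 replicate 2), and 0.816 for ethylene perception. For ethylene and jasmonate defence outputs it was 0.966, for flavonoids 0.882, for the circadian clock 0.575 and for senescence 0.539, where SAG21 rose by 2.71. For markers of guard cells it was 0.881, of vascular tissue 0.966, of trichomes 0.637, and of roots and flowers 0.637. The test pointed up with a negative median for ethylene biosynthesis (−0.19, mean 0.32), ethylene response factors (−0.05, mean 0.18), ethylene perception (−0.12, mean −0.25), defence outputs (−0.68), flavonoids (−0.13) and senescence (−0.53), and down with a positive median for guard cells (0.12, mean −0.40).

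**Figure D3:**
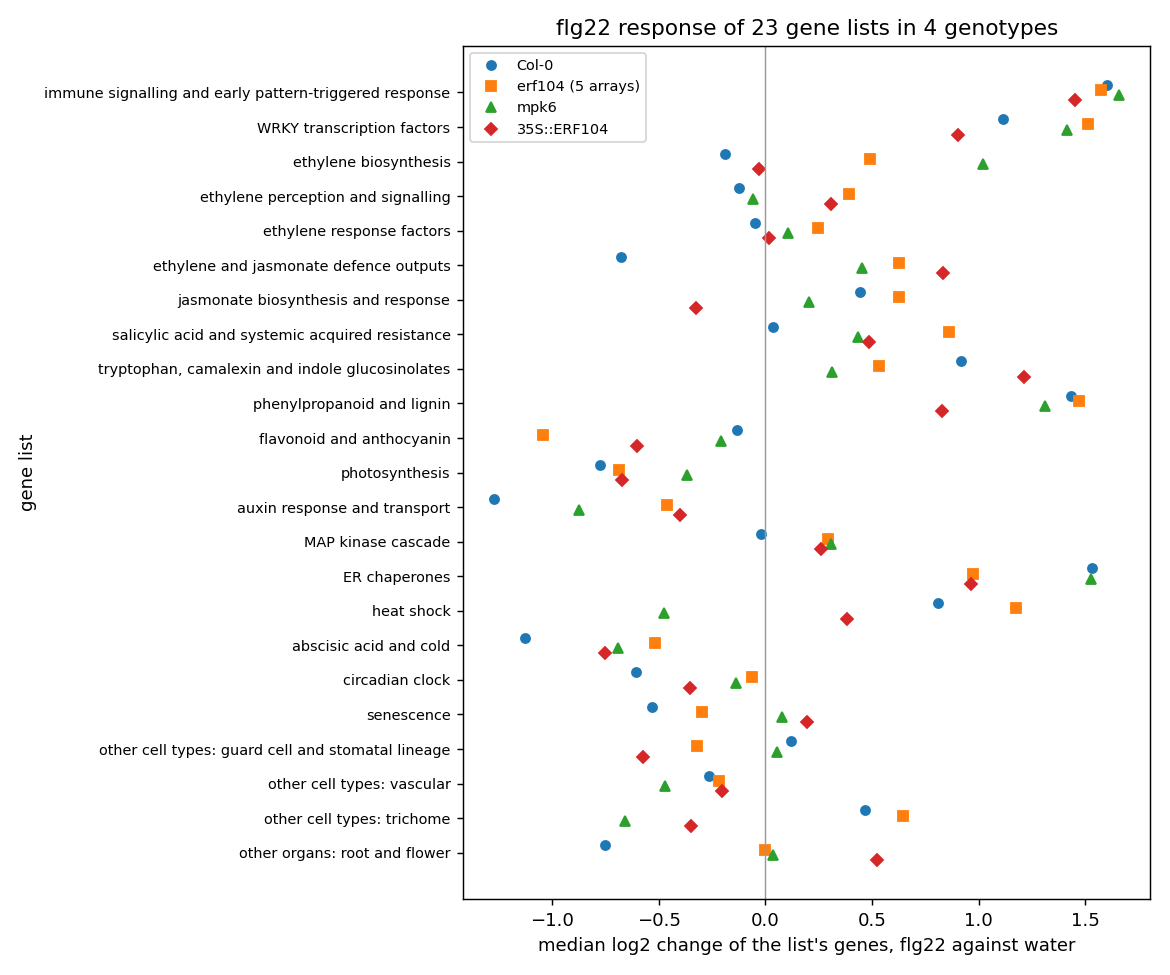
Median log2 change under flg22 of the genes in each of 23 lists, 1 marker per genotype (5 arrays for erf104, without replicate 2 under flg22; 6 for the others). The lists of immune signalling, WRKY, phenylpropanoid and ER chaperone genes lie above 0 in all 4 genotypes, at 1.60, 1.11, 1.43 and 1.53 in Col-0, and photosynthesis lies below 0 in all 4.

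The flg22 response in erf104 asks what remains of the response without ERF104. With 6 arrays limma called 0 probe sets, with 1754 at an unadjusted p under 0.05, and the methods' ANOVA called 0 after adjustment and 689 before it. Leaving out replicate 2 under flg22, 2209 passed: 992 rose and 1217 fell, 458 and 207 of them by more than 3-fold. In that fit AT1G30700 rose by 5.24 ± 0.400 (adjusted p 0.000118), AT3G18250 by 5.23 ± 0.271 (adjusted p 2.17e-05), and PRX52 (AT5G05340) by 4.84. AT2G36210 was at least 19.1-fold and AT2G45220 at least 16.3-fold higher. The largest falls, in AT3G30650, SKS2, AT3G42800 and AT5G50335, were in genes called absent under both treatments, and AT5G18090 was at least 1.76-fold lower. FRK1 rose by 3.46 ± 0.341 (adjusted p 0.000414; 2.61 and 0.601 with all 6 arrays), and PAL1 rose by 2.89. Immune signalling had 17 of 26 members rising, with a median of 1.57 (camera adjusted p 6.90e-16; p with estimated correlation 0.214); PROPEP3 was at least 12.4-fold and PROPEP2 at least 5.81-fold higher. Of the WRKY genes 12 of 20 rose (median 1.51), of the phenylpropanoid genes 9 of 16 (median 1.47) and of the ER chaperones 6 of 10 (median 0.97). Among ethylene biosynthesis genes 3 of 12 rose, ACS7 by 3.17 and ACS2 by 2.49. With all 6 arrays, 0 members of any list passed, and 10 members of immune signalling rose adjusted over the list alone (camera adjusted p 4.22e-08; p with estimated correlation 0.323).

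The flg22 response in mpk6 asks what remains without the kinase MPK6. Of the probe sets, 847 passed, 494 rising and 353 falling, and 330 and 125 of these changed by more than 3-fold. The count ran from 198 (without mpk6 flg22 replicate 1) to 1296 (without mpk6 water replicate 3) when 1 array was left out. After centring on the median, 265 rose and 91 fell. Without the trend limma called 0, with 2732 at an unadjusted p under 0.05. AT1G30700 rose by 5.87 ± 0.385 (adjusted p 3.04e-05), AT3G18250 by 5.85 ± 0.674 (adjusted p 0.000794), AT2G44370 by 6.51, AT1G26420 by 5.67, and AT2G36210 by at least 25.1-fold. The calls of AT2G44370 and AT1G26420 were lost without mpk6 flg22 replicate 1 (adjusted p 0.0573 and 0.0638). GA3OX1 (AT1G15550) fell by at least 10.5-fold (adjusted p 0.000324). The other large falls lost their call when 1 of 2 to 4 of the 6 arrays was left out: EXPA11 (at least 3.23-fold), ER (−3.80), AGP26 (at least 5.09-fold) and AT3G15570 (−2.98). FRK1 rose by 5.18 ± 0.761 (adjusted p 0.00354). Of the immune signalling genes 12 of 26 rose (19 adjusted over the list alone, median 1.66, camera adjusted p 2.89e-19; p with estimated correlation 0.119), PUB23 by 4.56. Of the ER chaperones 8 of 10 rose (median 1.52, camera adjusted p 3.23e-12; p with estimated correlation 0.142). Of the phenylpropanoid genes 7 of 16 rose (median 1.31, camera adjusted p 4.29e-12; p with estimated correlation 0.119), PAL1 by 2.97. Of the WRKY genes 6 of 20 rose (median 1.41, camera adjusted p 3.35e-11; p with estimated correlation 0.142), WRKY17 by 3.39 and WRKY22 by 3.17. MPK17 rose by 1.98 in the MAP kinase list.

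The flg22 response in 35S::ERF104 asks whether plants with high ERF104 still respond. Here 4177 probe sets passed, 1814 rising and 2363 falling, 432 and 262 of them by more than 3-fold. The median of all probe sets was −0.11, and after centring 2256 rose and 1793 fell. After quantile normalization 46.8% of the calls were rises. Without the trend limma called 1740. In 1 fit of all 24 arrays, which shares one variance, it called 144, against 773 in Col-0, 614 in erf104 and 333 in mpk6, and 860 in 1 fit of 23 arrays. The counts therefore do not rank the genotypes by their response. AT2G36690 rose by 5.78 ± 0.271 (adjusted p 2.95e-06), AT3G18250 by 5.19 ± 0.288 (adjusted p 5.81e-06) and AT2G44370 by 5.30 ± 0.614 (adjusted p 0.000247). PROPEP3 was at least 31.4-fold, GLR2.9 at least 5.49-fold and PROPEP2 at least 5.46-fold higher. The largest falls, in TRM13, CYP702A1, EXT12 and RIP4, were in genes called absent under both treatments, with the call of EXT12 lost without 1 of 4 arrays, and TRM22 was at least 2.81-fold lower. FRK1 rose 9.22-fold (log2 SE 0.274, adjusted p 6.15e-05) and ACS6 by 1.65 ± 0.355 (adjusted p 0.00834). Of the immune signalling genes 22 of 26 rose and 1 fell (median 1.45, camera adjusted p 2.16e-16; p with estimated correlation 0.327). Of the tryptophan and indole glucosinolate genes 15 of 20 rose and 1 fell (median 1.21, camera adjusted p 8.90e-11; p with estimated correlation 0.327), CYP81F2 by 2.53, while MYB34 was at least 4.36-fold lower. Phenylpropanoid genes rose in 11 of 16 cases, PAL1 by 1.88 and C4H by 1.63. All 10 ER chaperones rose, BIP3 by 2.46. Photosynthesis genes fell in 17 of 27 cases (median −0.67, camera adjusted p 3.04e-09; p with estimated correlation 0.406), PSBO1 by −0.87 and PSBO2 by −0.85. MPK6 itself rose by 0.49 ± 0.134 (adjusted p 0.0279), a call lost without 35S::ERF104 water replicate 2 (0.0971).

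Some of the genes followed throughout passed in few comparisons. WRKY33 changed under flg22 by 1.59 in Col-0, 1.73 in erf104, 1.62 in mpk6 and 1.68 in 35S::ERF104, with adjusted p of 0.116, 0.637, 0.245 and 0.0508. Without replicate 2 the change in erf104 was 1.86 (adjusted p 0.0523). ACS6 changed by 1.56 in Col-0, 0.52 in erf104 and 0.94 in mpk6, with adjusted p of 0.502, 0.757 and 0.211, and by 1.06 (0.0667) in erf104 without replicate 2. PR1 passed in none of the 13 comparisons, and its smallest adjusted p, 0.432, was that of the response in 35S::ERF104, with 24 and with 23 arrays. PDF1.2a and PDF1.2b passed for no flg22 response, with adjusted p of 0.638 or more.

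The interactions test whether the flg22 response of a line differs from that of Col-0. limma called 0 probe sets for erf104, 0 for mpk6 and 0 for 35S::ERF104, with 2863, 921 and 765 at an unadjusted p under 0.05. In the simulated data these fits missed most differences. With the residual SD as noise they recovered, in the same order, 0%, 8% and 6% of 4-fold and 26%, 20% and 22% of 8-fold differences. With the moderated SD they recovered 0%, 6% and 8%, and 30%, 14% and 28%. Calls of 0 therefore do not show that the lines respond like Col-0. With 23 arrays the calls were again 0, and 1393, 1615 and 1531 had an unadjusted p under 0.05. The methods' interaction F test called 0 in each after adjustment, and before it 878, 638 and 662 with a difference of more than 3-fold. For FRK1 the differences were −2.42 in erf104 (−1.58 with 23 arrays), 0.15 in mpk6 and −1.83 in 35S::ERF104, none past the threshold (adjusted p 0.411, 1.00 and 1.00; 23 arrays 0.873, 0.987 and 0.810). The composite list of probe sets past both thresholds in any genotype held 1000, of which 385 passed in Col-0, 0 in erf104, 455 in mpk6 and 694 in 35S::ERF104. Of these, 166 passed in 3 genotypes, 202 in 2 and 632 in 1, and 826 changed in the same direction in all 4. With 23 arrays the list held 1229, with 665 from erf104, and 156 passed in all 4 genotypes. Passing in 1 genotype alone is no test of a difference: adjusted over the list alone, the interaction test called 0 of the 1000 for each line, and with 23 arrays it called 1 for erf104. At an unadjusted p under 0.05 there were 174 for erf104, 50 for mpk6 and 125 for 35S::ERF104, and 129, 88 and 222 with 23 arrays. The list was selected on responses from the same arrays, so these counts have no simple value to be set against.

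Under water, the genotypes were compared to see what each does without the peptide. Relative to Col-0, the median of all probe sets was −0.51 in erf104, −0.35 in mpk6 and −0.48 in 35S::ERF104. It was 0.05, 0.05 and 0.04 after quantile normalization, so small falls are not read here. In 35S::ERF104 26 probe sets passed, 14 up and 12 down, all by more than 3-fold. The share of rises among the calls depended on the arrays and the scaling. With 23 arrays 532 were up and 800 down, with 13 and 1 after quantile normalization, and 25 and 8 after centring. The array left out of the 23 is in neither group, so the changes themselves stayed the same and only the shared variance estimate differed. Leaving out 1 of the 6 arrays compared gave 5 (without 35S::ERF104 water replicate 2) to 333 (without Col-0 water replicate 2). All 35S::ERF104 and erf104 water arrays have a high 25S rRNA signal, while Col-0 water replicates 1 and 2 have a low one. With this signal class as a block 7 probe sets passed for 35S::ERF104 and 2 for erf104, and 92 and 208 with 23 arrays. The defensin gene PDF1.2a (AT5G44420) was at least 86.7-fold higher (adjusted p 0.000128). The paralogue PDF1.2b, whose probe set may also match other defensin transcripts, was at least 102-fold higher (adjusted p 3.98e-06). AT3G23550 was higher by 4.71 ± 0.519 (adjusted p 1.54e-05). PDF1.2a, PDF1.2b, ERF104 and AT3G23550 kept their call when any 1 of the 6 arrays compared was left out. The other genes named here lost it without 1 of 2 to 5 of the 6 arrays. PLA2A was at least 12.2-fold, CYP81F2 10.5-fold, AT4G27300 4.58-fold, RHA2A 3.06-fold and MYB51 2.81-fold higher, each with an adjusted p of 0.0269 to 0.044; without 35S::ERF104 water replicate 3 that of CYP81F2 and MYB51 was 0.198. AT1G01300 was higher by 3.34 and RALFL22 by 3.25. AAC3 was lower by −2.39 and BEH4 by −2.36, and the other falls, in AT3G42500, CHIA, AT1G22460, AT1G49570, AT5G64100 and AT5G42830, were in genes called absent in both groups.

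The tryptophan, camalexin and indole glucosinolate list was higher in 35S::ERF104 water than in Col-0 water, with 3 of 20 members past the threshold (12 adjusted over the list alone), 17 of 20 positive and a median of 1.76 (camera adjusted p 5.99e-13; p with estimated correlation 0.0397). In erf104 water 5 probe sets passed (1434 with 23 arrays), and 0 to 309 when 1 array of the groups compared was left out. AT1G01300 was higher by 4.24, ECT3 by 2.38, EXPA5 by 2.41 and RHA2A by at least 4.01-fold. AT2G24320 was called absent in both groups. Each of these 5 calls was lost in at least 1 of the 6 fits that leave out an array (adjusted p up to 0.252). In mpk6 water 1 probe set passed, that of MAPKKK15 (AT5G55090, adjusted p 0.00784), a gene called absent in both groups. When 1 array of the groups compared was left out, 0 to 60 passed.

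Under flg22, 24 probe sets differed between 35S::ERF104 and Col-0, 22 up and 2 down. There were 100 with 23 arrays, and 7 to 162 when 1 array of the groups compared was left out. The median of all probe sets was −0.27. PDF1.2a was higher by 9.72 ± 1.14 (adjusted p 5.18e-05), PDF1.2b by 7.75 (adjusted p 7.31e-05), DIN11 (AT3G49620) by 6.50 (adjusted p 0.00222; 0.0525 without Col-0 flg22 replicate 1), and MYB51 (AT1G18570) by 5.99 ± 0.887 (adjusted p 0.00164). Both defensin genes were called absent on some Col-0 flg22 arrays. On replicates 1 and 2 PDF1.2a had signals of 19.7 and 10.6. The lowest signals among probe sets called present throughout the group were 278 and 113 there. Its size of 9.72 rests in part on signals below that level and is not comparable with the bound under water. AT1G64710 was at least 20.8-fold higher (adjusted p 5.18e-05). HEL was higher by 3.29, PAL4 lower by −3.08 and AT5G59515 at least 6.76-fold lower. Each of these 3 calls was lost without 1 of 4 to 5 of the 6 arrays, with adjusted p up to 0.198 for HEL, 0.345 for PAL4 and 0.328 for AT5G59515. The tryptophan and indole glucosinolate list had a median of 1.48 and 18 of 20 members positive, 1 past the threshold and 8 adjusted over the list alone (camera adjusted p 1.45e-17; p with estimated correlation 0.0107). The ethylene and jasmonate defence outputs had a median of 1.34 with 2 of 6 higher (camera adjusted p 0.00391; p with estimated correlation 0.0368). Phenylpropanoid genes had a median of −0.56 (camera adjusted p 0.00549; p with estimated correlation 0.553). In erf104, limma called 0 probe sets against Col-0 under flg22, with 2727 at an unadjusted p under 0.05. Leaving out 1 array of the groups compared gave 0 to 78 (78 without Col-0 flg22 replicate 3), and array weights gave 63. With 23 arrays it called 3, all lower in erf104: ERF104, AT3G62950 (at least 8.88-fold) and RDR2, called absent in both. In mpk6 it called 0, with 591 at an unadjusted p under 0.05, and 0 with 23 arrays, with 1121. Leaving out 1 array of the groups compared gave 0 to 11 (11 without Col-0 flg22 replicate 3). The methods' ANOVA called 0 in both after adjustment, and 102 in erf104 and 256 in mpk6 before it.

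Whether high ERF104 moves the same genes as flg22 was asked by overlap. Of the 14 probe sets higher in 35S::ERF104 water, 4 also rose under flg22 in Col-0, where 0.221 would be met by chance for independent lists. No probe set fell in both. The overlap ran from 0 (without 35S::ERF104 water replicate 1) to 31 (without Col-0 water replicate 2) when 1 array of the groups compared was left out. With 23 arrays 62 were up in both (8.40 for independent lists), 5 down in both (2.22) and 3 opposite. Both comparisons share the 3 Col-0 water arrays, so the lists are not independent. Across probe sets, which are not independent replicates, the correlation was 0.57. Simulated unchanged groups that share a control group in the same way gave 0.50, with a 95th percentile of 0.75. The covariance was 1.01, against 0.407 in the simulated groups, with a 95th percentile of 0.758. The correlation thus lies within the simulated range and the covariance above it. The simulated groups were drawn from arrays of all groups, while the real shared group, Col-0 water, had the least alike arrays of the water groups. A larger spread in the shared group raises the covariance, so this range does not decide and the cause is left open. The flg22 response in erf104 shares no array with the 35S::ERF104 effect. Against it the overlap was 0 and the correlation −0.45 with all arrays. With 23 arrays 70 were up in both, where 23.2 would be met by chance for independent lists, 4 down in both (42.8) and 84 opposite, with a correlation of −0.00. The interactions of erf104 and mpk6 correlated at 0.68 and shared 0 calls. Simulated groups that share arrays in the same way and hold the outlying array gave 0.40 (95th percentile 0.65). With 23 arrays the correlation was 0.63 against 0.47 (95th percentile 0.70). Their covariance was 1.63 against 0.784 (95th percentile 1.63), and with 23 arrays 1.13 against 0.823 (95th percentile 1.42), so with 23 arrays neither lies beyond the simulated range. The simulated group for erf104 flg22 was matched to each set of arrays after the first values had been seen. The shared Col-0 groups were not matched in their spread, so a value beyond the simulated range does not decide here either.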

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

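The tests on the array that stands apart, and all splits of the arrays, were chosen after the results were seen. The tests on the gene lists in 35S::ERF104 were set before their values were seen, and a condition added later is named where it applies.

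Expression of host genes on erf104 flg22 replicate 2 stands apart from all other arrays, which is why it is treated separately. Its 18 bacterial control probe sets, which no comparison uses, had a median signal of 157831, above that of each water array, of which the highest was 14012.5. The ratio to the highest other array was 11.3, and a large share of control transcript relative to plant RNA is a candidate explanation. How it would act was not tested: the scaling trims 2% of the values at each end, so the control signals do not enter it, and the median signal of this array, 280, was not low. Its highest correlation with any other array was 0.250, where arrays of one group otherwise reached at least 0.614 with each other. This restates that the array stands apart, so whether it also carries a wrong label is left open. Why control transcripts were so high is left open, and no biological explanation was tested. With this array 0 probe sets passed limma for the flg22 response in erf104 (1754 at an unadjusted p under 0.05, and 0 by the methods' ANOVA after adjustment), and 2209 without it.

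A difference between genotypes in the flg22 response was met in 10 tests of gene lists at the preset correlation of camera, although no member passed in any of them. For erf104 the lists and their adjusted p were jasmonate (median difference −0.58, 0.0107), tryptophan and indole glucosinolates (−1.40, 0.00380), phenylpropanoids (−0.996, 0.000372), photosynthesis (−0.37, 0.00380) and ER chaperones (−1.16, 0.000249). The p with estimated correlation was 0.920, 0.662, 0.662, 0.920 and 0.662. With 23 arrays the adjusted p of these lists at the preset correlation was 0.963, 0.0877, 0.0266, 0.888 and 0.00171, so for 3 of the 5 the call rests on the array that stands apart. For mpk6 they were tryptophan and indole glucosinolates (−0.37, 0.0435) and heat shock (−0.70, 0.0435), with a p of 0.868 and 0.227 under estimated correlation. For 35S::ERF104 they were jasmonate (−0.82, 3.96e-06), phenylpropanoids (−0.71, 8.96e-07) and ER chaperones (−0.59, 0.000679), with a p of 0.691, 0.550 and 0.827 under estimated correlation. The median of all probe sets was 0.44, 0.22 and 0.15 in the interactions of erf104, mpk6 and 35S::ERF104. Over the 13 comparisons 72 list shifts were called. Of 100 splits of the arrays 35 gave as many, with up to 113 in another split. Such splits can hold real differences between groups, so they do not decide, and chance is not excluded for the number of shifts.

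The tryptophan, camalexin and indole glucosinolate list was higher in 35S::ERF104 water than in Col-0 water, and the Col-0 water arrays were the least alike of the water groups. Of these, replicates 1 and 2 also had a low 25S rRNA signal, while all 35S::ERF104 arrays had a high one. Scaling between arrays as the whole cause is argued against. Quantile normalization moved the median of all probe sets in this comparison from −0.48 to 0.04, while the median difference of the list went from 1.76 to 2.07 (camera adjusted p 1.90e-09; p with estimated correlation 0.119; 2 members past the threshold). Taken per array, the list median then differed by 1.80 ± 0.210 (SE of 3 and 3 arrays), and the lowest of 35S::ERF104, 9.87, lay above the highest of Col-0, 8.63. How far the quality of the Col-0 arrays contributes stays open. Against erf104 water, a comparison with no Col-0 array and 6 arrays of high 25S rRNA signal, the list had a median difference of 0.938, with 17 of 20 members positive (camera adjusted p 2.58e-12; p with estimated correlation 0.336). There 3 members passed, CYP81F2, TSA1 and IGMT2, and the list medians per array differed by 0.49 ± 0.143. Both tests met the bound set beforehand, a median of 0.3 with an adjusted p under the threshold at the preset correlation. That correlation may be too lenient. In 35 of 100 splits of the arrays as many list shifts were called as in the real groups. Such splits can hold real differences between groups, so they do not show whether it is too lenient. With this open, a further condition was added after the results were seen. It was first the p with estimated correlation, which neither test passes, and then that the difference per array exceed the bound by more than 2 SE, which only the test on scaling passes. The difference from erf104 water, 0.49 ± 0.143 per array, involves no Col-0 array. Since erf104 is a knockout of the same gene, a list lowered by that loss would give such a difference too. It therefore does not decide whether the array quality of Col-0 is the whole cause of the difference from Col-0. It also misses the later condition, and the camera p with estimated correlation misses the threshold. How much of the larger difference from Col-0 comes from array quality or from high ERF104 cannot be told apart, and both may contribute.

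The phenylpropanoid list had a smaller flg22 response in 35S::ERF104 than in Col-0 (median −0.71, camera adjusted p 8.96e-07; p with estimated correlation 0.550), with 0 members past the threshold by limma, which called 0 of all probe sets (765 at an unadjusted p under 0.05). All 3 interactions share the 6 Col-0 arrays. Set against the response in mpk6 in place of Col-0, the median difference was −0.542 with 2 of 16 members positive (camera adjusted p 0.00122; p with estimated correlation 0.587). This met the bound set beforehand, a median of −0.3 or lower at the preset correlation, and the difference per array of −0.67 ± 0.323 leaves it open under the same later condition. The Col-0 arrays and a weaker response in plants with high ERF104 cannot be told apart here, since the p with estimated correlation misses the threshold and limma called 0 probe sets in that comparison (1078 at an unadjusted p under 0.05).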

How the results depend on the processing

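The alternatives with 23 or 20 arrays, array weights, the 25S rRNA class and adjustment over 6 tests were chosen after the data had been seen. No single gene named here that passed changed sign under an alternative. The share of rises did change: 1814 rose and 2363 fell in 35S::ERF104 under flg22, but 2256 and 1793 after centring, and 14 were up and 12 down for 35S::ERF104 under water, but 532 and 800 with 23 arrays. After quantile normalization the median of all probe sets went from 0.44, 0.22 and 0.15 to −0.17, −0.06 and −0.04 in the interactions of erf104, mpk6 and 35S::ERF104. Under water it went from −0.51, −0.35 and −0.48 to 0.05, 0.05 and 0.04. For the single genes named in the text, 2170 values under an alternative kept their side of the threshold, 402 no longer passed, 169 newly passed and 49 moved by more than their SE. The cause was not tested for the changes below, apart from the fewer or differently weighted arrays that some alternatives hold by construction.

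Scaling changed these counts. After quantile normalization 256 probe sets passed for the flg22 response in Col-0, 14 for 35S::ERF104 under water and 8 under flg22. After centring on the median 274 passed for the response in Col-0, 356 for mpk6, 18 for erf104 under water and 12 for 35S::ERF104 under flg22. With a pseudocount 2 passed for erf104 under water, 0 for mpk6 under water (limma, 2365 at an unadjusted p under 0.05), 15 for 35S::ERF104 under water and 37 under flg22, and 2 were shared between 35S::ERF104 water and the Col-0 response. With the stricter filter on detection calls 17 passed for erf104 under water, 0 for mpk6 under water (limma, 557 at an unadjusted p under 0.05) and 10 for 35S::ERF104 under water, and 1 was shared. The cause was not tested.

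Without the trend in the variance prior limma called 0 for the response in Col-0 (2145 at an unadjusted p under 0.05), 0 in mpk6 (2732) and 1740 in 35S::ERF104. It called 0 for erf104 under water (4168) and 8 for 35S::ERF104 under flg22, and the composite list held 558. In 1 fit of all 24 arrays 773 passed for the response in Col-0, 614 in erf104, 333 in mpk6 and 144 in 35S::ERF104. With only the groups of the contrast 74 passed for erf104 under water, 0 for mpk6 under water (limma, 1740 at an unadjusted p under 0.05) and 82 for 35S::ERF104 under flg22. With a 2-fold threshold the composite list held 2222. With the correlation estimated from the data 8 list shifts passed, against 72. The cause was not tested.

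With the replicate number as a block 1101 passed for the response in Col-0, 2053 in mpk6, 41 for erf104 under water, 49 for 35S::ERF104 under water and 48 under flg22, and 12 were shared with the Col-0 response. The flg22 array of the same number was the closest to a water array in 1, 0, 2 and 1 of 3 cases in Col-0, erf104, mpk6 and 35S::ERF104. The numbers were therefore not taken to pair the arrays, although so few cases do not exclude a shared batch. In Col-0 and mpk6, under both treatments, replicates 1 and 2 had a low 25S rRNA signal and replicate 3 a high one. The number thus overlaps with that signal class there, and these counts are given only as an alternative.

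The methods' ANOVA without adjustment gave, by more than 3-fold, 1205 for the response in Col-0, 689 in erf104 and 892 in mpk6. It gave 878, 638 and 662 for the interactions of erf104, mpk6 and 35S::ERF104. Under water it gave 1762 for erf104, 884 for mpk6 and 2094 for 35S::ERF104, and under flg22 102, 256 and 830. The composite list held 2748. After adjustment it gave 0 for Col-0, 1 for mpk6 and 366 for 35S::ERF104 among the responses. Under water it gave 1 for erf104, 0 for mpk6 and 0 for 35S::ERF104, and under flg22 0 for 35S::ERF104. The 0 counts stand beside limma's 385, 1, 26 and 24 and the unadjusted 1205, 884, 2094 and 830. The variance of single probe sets is not moderated in this test.

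With 23 arrays 2209 passed for the response in erf104 (665 by more than 3-fold), 1434 for erf104 under water (820) and 3 under flg22 (3), 1332 for 35S::ERF104 under water (905) and 100 under flg22 (76). ERF104 in erf104 was −2.36 under water and −4.00 under flg22. It was called absent in erf104 and in Col-0 water, so here and below its values in erf104, and in 35S::ERF104 under water, are fitted ones and no measure of a fold. The overlap was 67 with the Col-0 response and 74 with that of erf104. In 1 fit of 23 arrays 2386 passed for the response in Col-0, 672 in erf104, 1291 in mpk6 and 860 in 35S::ERF104. With array weights the counts were 939 for the response in Col-0, 3016 in erf104 and 1544 in mpk6. They were 1 for the erf104 interaction, 415 for erf104 under water and 63 under flg22, and 131 for 35S::ERF104 under water and 912 under flg22. ERF104 in erf104 was −2.65 and −3.59, and MPK6 in mpk6 under water −2.0.

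With the 25S rRNA class as a block and 24 arrays 1113 passed for the response in Col-0, 2076 in erf104 and 2292 in mpk6, 2 for erf104 under water, and 7 and 9 for 35S::ERF104 under water and flg22. Among the erf104 arrays only flg22 replicate 2 has a low signal, so in that response the block acts much as leaving it out does. Without that array the erf104 response holds 1 class and no block, so neither count is a separate check of that response. With 23 arrays 2209 passed for the response in erf104, 208 for erf104 under water and 1 under flg22, 4 for mpk6 under water and 1 under flg22, and 92 for 35S::ERF104 under water and 47 under flg22. ERF104 in erf104 was −2.73 and −4.36, and MPK6 in mpk6 under water −1.69 with an adjusted p of 0.0253. Within arrays of low 25S rRNA signal 1049 passed for the response in Col-0, 8 for mpk6 under water and 3 under flg22, and MPK6 was −2.21. Within arrays of high signal Col-0 and mpk6 each have 1 array per treatment, assumed to vary like the other groups. There 7513 passed for the response in Col-0, 3402 in erf104 and 275 in mpk6, and 2845, 939 and 3162 for the 3 interactions. Under water 8621, 5692 and 9167 passed for erf104, mpk6 and 35S::ERF104, and under flg22 2, 6 and 78. ERF104 in erf104 was −3.22 and −4.13. All counts there except that of the erf104 response involve a group of 1 array. Those for the Col-0 response, the interactions and the lines under water involve Col-0 water replicate 3, the lone Col-0 water array.

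Leaving out erf104 flg22 replicate 2, Col-0 water replicates 1 and 3 and Col-0 flg22 replicate 1 leaves 20 arrays and 1 Col-0 water array, assumed to vary like the other groups. With these 904 passed for the response in Col-0, 1574 in erf104, 2394 in mpk6 and 1735 in 35S::ERF104, and 3, 1 and 4 for the interactions of erf104, mpk6 and 35S::ERF104. Under water 137, 11 and 46 passed for the 3 lines, and under flg22 1 for erf104 and 69 for 35S::ERF104. ERF104 in erf104 was −2.86 and −3.60, and MPK6 in mpk6 under water −2.18. Adjusted over the 6 targeted tests the differences were −2.36 and −2.88 for ERF104 in erf104 and −1.69 and −1.47 for MPK6 in mpk6, all past the threshold, and with 23 arrays −2.36, −4.00, −1.69 and −1.47.

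Leaving out in turn each array of the groups compared gave 239 (without Col-0 flg22 replicate 2) to 681 (without Col-0 water replicate 3) for the response in Col-0. It gave 0 to 2209 in erf104 (without flg22 replicate 2), 198 (without flg22 replicate 1) to 1296 (without water replicate 3) in mpk6, and 2986 to 3868 in 35S::ERF104. The interactions gave 0 to 1 for erf104 (without Col-0 water replicate 3), 0 to 3 for mpk6 and 0 to 2 for 35S::ERF104 (both without Col-0 water replicate 2). Under water the range was 0 to 309 for erf104, 0 to 60 for mpk6 and 5 to 333 for 35S::ERF104, each highest without Col-0 water replicate 2. The array erf104 flg22 replicate 2 is in none of these groups, and without it 1434 passed for erf104 and 1332 for 35S::ERF104. Under flg22 it was 0 to 78 for erf104, 0 to 11 for mpk6 and 7 to 162 for 35S::ERF104, each highest without Col-0 flg22 replicate 3. The composite list held 881 to 1229. ERF104 in 35S::ERF104 was 6.74 to 7.85 under water and 6.98 to 7.83 under flg22, in erf104 −3.04 to −1.93 under water and −4.00 to −2.22 under flg22, and MPK6 in mpk6 −1.98 to −1.44 and −1.72 to −1.25. The overlap with the Col-0 response was 0 to 31, with that of erf104 0 to 3, and that of the erf104 and mpk6 interactions 0 to 0. With 23 arrays in every fit the overlap was 67 with the Col-0 response and 74 with that of erf104.

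The other value table was not used for a test, because it holds group values only. No filter is the setting reported, and each gene of the lists has 1 probe set, so the mean over probe sets was not run. Signal over background limits the Col-0 comparisons most: 2572 probe sets were called present or marginal on all Col-0 water arrays, against 9338 to 12048 in the water arrays of the other genotypes.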

Other observations

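The comparison of 35S::ERF104 with erf104, that of the erf104 and mpk6 responses, and all splits of the arrays, were chosen after the data had been seen. Between 35S::ERF104 and erf104 under water no Col-0 array is needed, and 35 probe sets passed limma, 32 higher and 3 lower in 35S::ERF104 (2177 at an unadjusted p under 0.05). ERF104 was called absent in erf104 (adjusted p 4.72e-09). PDF1.2a was higher by 8.62 ± 0.895 (adjusted p 0.00129), DIN11 by 6.11 (adjusted p 0.000597), AT3G23550 by 4.29 (adjusted p 0.000218), CYP81F2 by 3.47 (adjusted p 0.0181), BCAT-2 by 3.31 (adjusted p 0.0256), NRT2.1 by 2.77 (adjusted p 0.0459), NRT1.8 by 2.49 and IGMT2 by 2.19 (adjusted p 0.00686). SUFE2 and AACT1, called absent in erf104, were also higher, and ELIP2, called absent in 35S::ERF104, was lower. PDF1.2a and AT3G23550 thus differ from both Col-0 and erf104. CYP81F2 does so less firmly, since its call against Col-0 was lost without 35S::ERF104 water replicate 3 (adjusted p 0.198). The flavonoid list had a median of −1.02 with 0 of 14 members positive (camera adjusted p 1.22e-07; p with estimated correlation 0.336). Lists pointing up had a camera adjusted p of 0.0196 (ethylene response factors), 0.0262 (defence outputs), 0.0322 (immune signalling), 0.0459 (ethylene perception) and 0.0459 (circadian clock). Their p with estimated correlation was 0.336 to 0.865. The tryptophan list is given above. Between the flg22 responses of erf104 and mpk6, 1 probe set passed (1016 at an unadjusted p under 0.05).

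Splits of the arrays ask how often other groupings of the same arrays give as many calls. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05, so only the values are given. The real count and the highest of the other 9 were 422 and 3 for the response in Col-0, 847 and 0 in mpk6, 4177 and 0 in 35S::ERF104, and 0 and 0 in erf104. Under water they were 5 and 0 for erf104, 1 and 1 for mpk6, and 26 and 0 for 35S::ERF104, and under flg22 0 and 3286 for erf104, 0 and 4 for mpk6, and 24 and 0 for 35S::ERF104. A result as large came from 1 split for Col-0, mpk6 and 35S::ERF104 responses, erf104 under water and 35S::ERF104 under both treatments, from 3 for mpk6 under water and from 10 elsewhere. The split with 3286 sets Col-0 flg22 replicates 1 and 2 with erf104 flg22 replicate 2, the arrays of low 25S rRNA signal, against the others. It points to a structure of the arrays other than genotype. With the 25S rRNA class as a block and 23 arrays, 1 probe set passed in that comparison.

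For the interactions the real counts are 0, which each of 100 splits reaches whatever the data hold, so this comparison decides nothing about chance. The highest other splits gave 4281 for erf104, 18 for mpk6 and 464 for 35S::ERF104. The split with 4281, like that with 3286, sets Col-0 flg22 replicates 1 and 2 with erf104 flg22 replicate 2 against the other flg22 arrays. The outlying array and the low 25S rRNA signal fall on the same side there, and a structure of the arrays is shown without saying which of these it follows. The split with 464 exchanges the flg22 arrays of 35S::ERF104 and Col-0 whole, so it holds the difference between the lines and not chance alone. The composite list of 1000 was reached in 1 of 100 splits, the real one, with 898 the highest other. The other splits may keep the real groups in some genotypes, so 898 is no chance value and this comparison does not decide. Regrouped arrays of a single genotype gave up to 3 calls. The 4 shared calls between 35S::ERF104 water and the Col-0 response were reached in 2 of 100 splits, with 38 the highest other. Splits deal arrays of different groups together and can hold real differences between groups, as that with 464 does. This share therefore does not decide whether chance explains the overlap. Without 35S::ERF104 water replicate 1 the overlap was 0, both comparisons share the Col-0 water arrays, and their correlation of 0.574 lies below the simulated 95th percentile of 0.746. Their covariance of 1.01 lies above that of 0.758, but the simulated groups were not matched to the larger spread of the Col-0 water arrays. The cause of the overlap is left open. The overlap with the erf104 response and that between the erf104 and mpk6 interactions were 0 in each of 100 splits, with 0 the highest other. A real overlap of 0 is reached by any split, so this too decides nothing.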
